A study of Mus musculus with 31 samples.

How the data were processed

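The data are gene expression arrays of mouse skin, 1 array per mouse sample, from female SHARPIN-deficient cpdm mice and female C57BL/6J wild type mice of 5 ages. Skin was kept in RNAlater and RNA extracted with TRIzol, per the labels' protocols. The deposited values are log2 intensities that the authors made with Affymetrix Expression Console 1.2 and RMA, per the submitters' processing notes. The RMA version is not stated there, nor whether all arrays were normalized together. The deposited values were given to 2 decimals for 35556 probe sets in 31 arrays. The labelling protocol names a kit for 3' arrays while the probe sets are those of a whole-transcript array, and this was left unresolved. Detection calls, scan dates and batches are not given in the sources used here, so no batch could be tested.

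Of the 35556 probe sets, 23410 were listed with genes, 21789 of them with a single gene and 1621 with several, and 12146 had no gene name. Entrez identifiers of 21698 single-gene probe sets were found in the RefSeq gene table, which gave the symbols used. Where a gene had several probe sets (998 genes), the 1 with the highest mean signal was used, which left 19939 genes. No filter on dim signals was applied in the main comparison. Samples were grouped by genotype and age, 10 groups in all, as the labels give them.

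Linear models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with a mean for each of the 10 groups and 21 residual degrees of freedom. Contrasts compared cpdm with wild type skin at each age. Moderated F tests asked whether the genotype difference changed from that at 2 weeks and whether genes changed with age within a genotype. P-values were adjusted by the Benjamini-Hochberg method over 19939 genes, and a gene was called at an adjusted p below 0.05. Tests were two-sided. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

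For 37 lists of marker and pathway genes with at least 5 measured members, camera from limma compared the members' differences with those of all other genes at each age, with a preset correlation of 0.01 between genes. Its p-values were adjusted over 185 tests. Calls with a correlation estimated from the data are given beside them. A list's count of changed members is given over all genes and adjusted over the list alone. The median, mean and test of a list differed in sign in 12 of the 185 tests, none of which was called. List means were also compared between ages by limma.

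The lists, the comparisons, the named-gene rule and all alternatives but the covariates for hair keratin and muscle signal were chosen before the data were examined. Genes were named by rule: at each age the 10 with the largest rise and the 10 with the largest fall among called genes whose arrays did not overlap, up to 4 members with the lowest p of each list, any member of the lists of blood endothelium, angiogenic factors, angiogenesis inhibitors and endothelial adhesion molecules, Sharpin, Nnt and Samsn1, and the 10 with the lowest p for the interaction and for age in each genotype. Clones and gene models were left out. Xist and Kdm5d were looked up to check the sex of the mice.

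The same steps were tested on simulated data with 19939 genes, some of them changed by 0.5, 1 or 2 on the log2 scale. In the comparisons at single ages, 52.2% to 67.2% of the genes changed by 0.5 were recovered, 85.1% to 97.0% of those changed by 1 and 98.5% to 100% of those changed by 2, and 3.55% to 5.81% of the calls were false. For the interaction these shares were 22.4%, 80.6% and 100%, with 7.53% false calls. A list shifted by 0.5 was called at each age, with 0 of 36 other lists called by camera. The simulated genes varied independently of each other. The simulation therefore does not show how often lists of correlated genes are falsely called. In the real arrays 79 of 99 list calls were lost with an estimated correlation. Each simulated gene also had the same spread in all groups. In the real groups the median standard deviation of a gene ran from 0.0987 (wild type, 2 weeks) to 0.170 (wild type, 8 weeks). The simulated shares of false calls therefore hold only for groups of equal spread.

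Alternatives were a fit of only the arrays compared, the mean of a gene's probe sets, leaving out the dimmest 40% of genes, a trend and robust spread, array weights, repeated quantile normalization, centring each array on its median, the replicate number as a block, stricter thresholds, an estimated correlation, the fry test, lists without shared members, and leaving out each array in turn. Other splits of the arrays were counted for each comparison. Probe sets without a single gene name were used only in a count.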

Results

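RNA levels were measured across the genome in 31 skin samples of female mice, 1 array per sample, of 5 ages, from 2 to 10 weeks in steps of 2 weeks. The mutant mice, called cpdm, carry a mutation in Sharpin, a member of the linear ubiquitin chain assembly complex, and develop chronic proliferative dermatitis. The wild type mice are C57BL/6J. Each genotype had 3 arrays per age, except for 4 of wild type skin at 6 weeks, which makes 15 cpdm and 16 wild type arrays. Arrays of the same group correlated at r = 0.950 to 0.996 across genes, which are not independent replicates. The number of arrays per group limits the precision of every difference. Differences are given as log2 signal in cpdm minus wild type skin with ± the standard error (SE) of the limma fit. At 6 weeks n was 3 cpdm and 4 wild type arrays, and at every other age n was 3 and 3.

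Sharpin, the mutated gene, was lower in cpdm skin at every age. Its difference was -0.54 ± 0.09 at 2 weeks (limma, adjusted p = 0.0141), -0.81 ± 0.09 at 4 weeks, -0.62 ± 0.08 at 6 weeks, -0.69 ± 0.09 at 8 weeks and -0.69 ± 0.09 at 10 weeks (adjusted p = 1.53e-06). The highest of the 15 cpdm arrays (7.58) lay below the lowest of the 16 wild type arrays (7.89). At 2 weeks the Sharpin call ended without any 1 array other than cpdm replicate 3. The adjusted p was 0.0917 without cpdm replicate 1, 0.0834 without cpdm replicate 2, and 0.0635, 0.0824 and 0.0548 without wild type replicates 1, 2 and 3. Where the probes lie relative to the mutation is not given in the sources used here. Xist, the RNA of the inactive X chromosome, lay between 10.6 and 11.15 in all arrays, and the Y-linked gene Kdm5d between 3.34 and 4.04, as in female tissue. The mutant and wild type mice belong to different C57BL substrains, so substrain and Sharpin genotype cannot be separated in any comparison. Nnt and Samsn1, genes with known deletions in C57BL substrains, were looked up for that reason. Nnt was called only at 10 weeks (-0.91 ± 0.18, adjusted p = 0.000434), and at 8 weeks without wild type replicate 3 (adjusted p = 0.000731). With the muscle signal as a covariate, chosen after the data had been examined, its difference at 10 weeks turned to 0.28 (adjusted p = 0.397). Samsn1 was not called at any age, with differences of -0.03 to 0.11. Its signal was low, 3.79 to 4.24 in all arrays, close to that of Kdm5d, so a deletion might not show. Nnt signal at 10 weeks was 8.09 to 8.33 in cpdm and 9.03 to 9.17 in wild type arrays, so neither group lacked signal. These genes therefore cannot tell the substrains apart here.

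The comparison of the genotypes at each age asks when the skin of cpdm mice departs from that of wild type mice. Among 19939 genes, 11 differed at 2 weeks, 1378 at 4 weeks, 2881 at 6 weeks, 3468 at 8 weeks and 6502 at 10 weeks (limma, adjusted p below 0.05). Of these, 298 genes were higher and 207 were lower in cpdm skin at each of 4, 6, 8 and 10 weeks. The 6 genes higher at all 5 ages were Cxcl16, Hrnr, Il1f6, Serpina3n, Stfa3 and the unnamed clone 2610528A11Rik, and Sharpin was the 1 gene lower at all 5. The genes common to all ages were singled out after their values had been seen. Of the 1669 genes higher at 6 weeks, 955 were also among the 1435 higher at 8 weeks, where independent lists would share 120.1. Of the 2033 genes lower at 8 weeks, 1472 were also among the 3589 lower at 10 weeks, where independent lists would share 365.9. The groups' arrays did not overlap for 15.1% of genes at 2 weeks, 29.1% at 4, 22.4% at 6, 22.0% at 8 and 47.0% at 10. Chance gives 10% with 3 against 3 arrays and 5.71% at 6 weeks with 3 against 4.

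**Figure D1:**
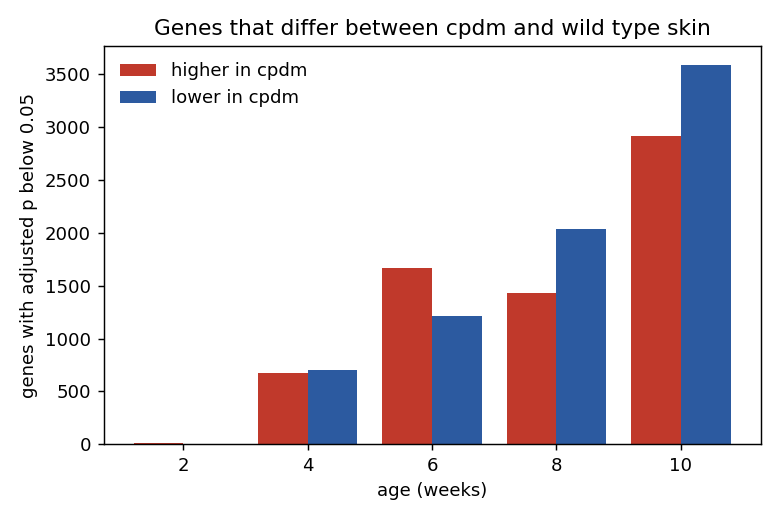
Number of genes with adjusted p below 0.05 (vertical axis) that were higher (red) or lower (blue) in cpdm than in wild type skin at each age in weeks (horizontal axis). The total rises from 11 at 2 weeks to 6502 at 10 weeks. With a covariate the count was not highest at 10 weeks. It was highest at 8 weeks with hair keratin signal (4634) and at 6 weeks with muscle signal (3797). Both covariates were chosen after the data had been examined.

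At 2 weeks, before most of the later changes, cpdm skin already had more RNA of inflammatory and cornified-layer genes. Stfa3, a stefin of the epidermis, was higher by 2.63 ± 0.43, Serpina3n, an acute-phase protease inhibitor, by 1.94 ± 0.32, the chemokine Cxcl16 by 0.90 ± 0.16 and the interleukin 36 cytokine gene Il1f6 by 0.90 ± 0.16. Hrnr (hornerin, a cornified envelope protein) was higher by 0.77 ± 0.15, B2m, the light chain of MHC class I, by 0.66 ± 0.13, and Serpina16 by 0.50 ± 0.10. Besides Sharpin, Gria2 (-0.66 ± 0.13) and Tekt5 (-0.65 ± 0.12) were lower. Probe sets of near-identical family members, such as the Stfa, Sprr, Lce, Gsdmc, Chil, Klk and Krtap genes, can share signal, so which member of such a family changed is uncertain. The interleukin 1 family list rose (median difference 0.20, adjusted p = 1.19e-09), with 1 of 16 members called over all genes and 4 adjusted over the list alone. It was the 1 list of 16 called at this age that held with an estimated correlation (adjusted p = 0.0398). NF-kB target genes also rose (median 0.27, adjusted p = 5.84e-09), with 0 of 20 members called by limma over all genes and 2 adjusted over the list alone (adjusted p = 0.0876 with an estimated correlation). Epidermal differentiation genes rose by a median of 0.26, with 1 of 20 members called over all genes and 1 adjusted over the list alone (adjusted p = 7.18e-09, and adjusted p = 0.0594 with an estimated correlation). Melanocyte and pigment genes were lower by a median of -0.61, with 0 of 13 members called over all genes and 1 adjusted over the list alone (adjusted p = 1.82e-05, and adjusted p = 0.337 with an estimated correlation). Skeletal muscle genes were higher by a median of 0.26 with 0 of 20 members called by limma over all genes or adjusted over the list alone (adjusted p = 1.73e-06, and adjusted p = 0.449 with an estimated correlation). An unadjusted p below 0.05 was reached by 1035 of 19939 genes, close to the share of 0.05 that chance alone gives. The count of 11 rests on each array: 4 genes were called without cpdm replicate 1, 4 without cpdm replicate 3, and 0 without cpdm replicate 2 or without wild type replicate 1, 2 or 3. Each gene named here lost its call without cpdm replicate 2, with adjusted p from 0.0834 for Sharpin to 0.517 for B2m, and 0 genes passed at adjusted p below 0.01. Array weights gave 59 genes.

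At 4 weeks, cpdm skin had more RNA of stressed keratinocytes, NF-kB targets and chemokines. The largest increases among genes named by rule were Stfa3 (4.38 ± 0.43), Gsdmc (4.22 ± 0.28, a gasdermin), the wound keratin Krt16 (3.72 ± 0.62), Pyy (3.67 ± 0.32, peptide YY), Gsdmc2 (3.42 ± 0.30), the wound keratin Krt6b (3.38 ± 0.46), the macrophage elastase Mmp12 (3.32 ± 0.30) and the chemokine Ccl17 (2.94 ± 0.26). The largest decreases were Ppp1r3c (-1.71 ± 0.26, a glycogen-targeting phosphatase subunit), Cyp2g1 (-1.70 ± 0.38), the lysozyme Lyz1 (-1.70 ± 0.48), Angptl1 (-1.68 ± 0.29) and Cyp2f2 (-1.63 ± 0.36). In the keratinocyte stress and hyperplasia list, 13 of 25 members rose over all genes and 17 adjusted over the list alone, with a median of 1.24 (adjusted p = 3.41e-14, and adjusted p = 0.026 with an estimated correlation). In the NF-kB target list, 13 of 20 rose and 15 adjusted over the list alone, among them Lcn2 (1.72 ± 0.28), Nfkbie (1.37 ± 0.21) and Nfkb2 (1.03 ± 0.16). The list's median was 0.59 (adjusted p = 2.62e-14, and adjusted p = 0.0329 with an estimated correlation). Of the chemokines, 9 of 20 rose over all genes and 9 adjusted over the list alone, such as Ccl19 (1.93 ± 0.35), Ccl2 (1.63 ± 0.29) and Cxcl16 (1.55 ± 0.16), with a median of 0.43 (adjusted p = 1.39e-07, and adjusted p = 0.0447 with an estimated correlation).

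Markers of dendritic cells and of type 2 responses rose at 4 weeks as well. Of the type 2 cytokines and targets, 7 of 21 rose over all genes and 7 adjusted over the list alone, including Il13ra2 (1.83 ± 0.24), Ccl22 (1.65 ± 0.24) and the eosinophil chemokine Ccl11 (1.25 ± 0.24). That list's median was 0.41 (adjusted p = 5.77e-08, and adjusted p = 0.0582 with an estimated correlation). Of the dendritic and Langerhans cell markers, 4 of 15 rose and 8 adjusted over the list alone, such as Itgax (1.65 ± 0.26) and Ccr7 (1.12 ± 0.14), with a median of 0.45 (adjusted p = 3.08e-08, and adjusted p = 0.0876 with an estimated correlation). Neutrophil (median 0.37, adjusted p = 7.84e-06), T cell (0.22, 0.00108) and eosinophil markers (0.24, 0.00161) were called higher too, with 3 of 14, 1 of 15 and 2 of 7 members called over all genes and 6, 3 and 3 adjusted over the list alone. With an estimated correlation these 3 calls ended (adjusted p = 0.117, 0.2 and 0.176). Macrophage (adjusted p = 0.314), mast cell (0.161) and B and plasma cell markers (0.176) were not called. The macrophage list, with a median of 0.07 in all arrays, was called higher without wild type replicate 3 (median 0.38, adjusted p = 0.0245). Fibroblast and extracellular matrix genes fell by a median of 0.42 on the log2 scale, with 3 of 23 lower and 1 higher over all genes and 5 lower and 1 higher adjusted over the list alone (adjusted p = 0.00104, and adjusted p = 0.579 with an estimated correlation). Among them, Eln (elastin) fell by 1.05 ± 0.20 and Fap (fibroblast activation protein) by 0.94 ± 0.21. Of the 1378 genes, 678 were higher and 700 lower (779 and 618 with each array centred on its median), and 182 differed at least 2-fold. With 1 array left out, 882, 646 and 618 genes were called without cpdm replicates 1, 2 and 3 and 871 and 629 without wild type replicates 1 and 2, while array weights gave 2925. The call ended for Cyp2g1 without cpdm replicate 3 (adjusted p = 0.0739), and for Lyz1 without cpdm replicate 1 (0.0939), 2 (0.0777) or 3 (0.0816) or wild type replicate 2 (0.106) or 3 (0.118).

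At 6 weeks, genes of the cornifying and stressed epidermis and of type 2 inflammation were higher in cpdm skin, and hair keratin genes were far lower. The largest increases were Stfa3 (6.00 ± 0.41), the chitinase-like Chil4 (5.99 ± 0.41), Krt6b (5.79 ± 0.43), Gsdmc (5.77 ± 0.26), Gsdmc2 (4.52 ± 0.28), Sprr1b (4.32 ± 0.38, a cornified envelope precursor) and Krt16 (4.00 ± 0.58). In the keratinocyte stress and hyperplasia list, 18 of 25 members rose and 19 adjusted over the list alone, with a median of 1.45 (adjusted p = 1.5e-21, and adjusted p = 0.00475 with an estimated correlation). Of the interleukin 1 family, 12 of 16 rose over all genes, with 12 higher and 1 lower adjusted over the list alone, including the interleukin 36 genes Il1f8 (3.46 ± 0.18) and Il1f6 (3.06 ± 0.15), with a median of 1.14 (adjusted p = 4.1e-14, and adjusted p = 0.0181 with an estimated correlation). Of the type 2 cytokines and targets, 12 of 21 rose and 14 adjusted over the list alone, with a median of 0.94 (adjusted p = 2.12e-10, and adjusted p = 0.0329 with an estimated correlation). Chil3 (3.03 ± 0.35) and Ccl17 (2.96 ± 0.24) were among them. Of the eosinophil markers, 5 of 7 rose and 5 adjusted over the list alone, with a median of 0.77 (adjusted p = 2.55e-06, and adjusted p = 0.0447 with an estimated correlation). They included Alox15 (3.17 ± 0.24), Prg2 (0.90 ± 0.12, major basic protein) and Siglecf (0.72 ± 0.12).

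Barrier genes changed together at 6 weeks. Of the epidermal differentiation genes, 14 of 20 rose and 14 adjusted over the list alone, with a median of 0.82 (adjusted p = 6.04e-13, and adjusted p = 0.0291 with an estimated correlation), such as Lce1f (2.11 ± 0.22), Casp14 (2.07 ± 0.12) and Hrnr (1.86 ± 0.14). Of the epidermal lipid barrier genes, 12 of 15 rose and 15 adjusted over the list alone, with a median of 0.73 (adjusted p = 1.2e-11, and adjusted p = 0.0291 with an estimated correlation). Of the hypoxia and glycolysis genes, 12 of 18 rose and 14 adjusted over the list alone, with a median of 0.65 (adjusted p = 1.76e-13, and adjusted p = 0.0447 with an estimated correlation), such as the oxygen sensor Egln3 (2.89 ± 0.21) and the glucose transporter Slc2a1 (1.99 ± 0.13). Of the hair keratins and keratin-associated proteins, 25 of 28 fell and 28 adjusted over the list alone, with a median of -3.22 (adjusted p = 2.62e-14, and adjusted p = 0.286 with an estimated correlation). Krt25 fell by 4.22 ± 1.08, Krt26 by 4.22 ± 1.15 and Krtap6-3 by 3.85 ± 0.87. Hair follicle stem cell and growth genes also fell, 11 of 24 lower and 1 higher over all genes and 14 lower and 1 higher adjusted over the list alone, with a median of -0.68 (adjusted p = 1.78e-06, and adjusted p = 0.0876 with an estimated correlation). Interferon response genes fell by a median of 0.79, with 5 of 21 lower over all genes and 5 adjusted over the list alone (adjusted p = 0.000672, and adjusted p = 0.579 with an estimated correlation), Ifit3 by 2.31 ± 0.55. Of the 2881 genes, 1669 were higher and 1212 lower (1952 and 1045 with centred arrays), and 528 differed at least 2-fold. Without cpdm replicate 3, 1457 genes were called and Krt25 (adjusted p = 0.0641) and Krt26 (0.0798) were not. Krt26 was not called without cpdm replicate 2 either (adjusted p = 0.0653). With only the arrays of 6 weeks in the fit 1779 genes were called.

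**Figure D2:**
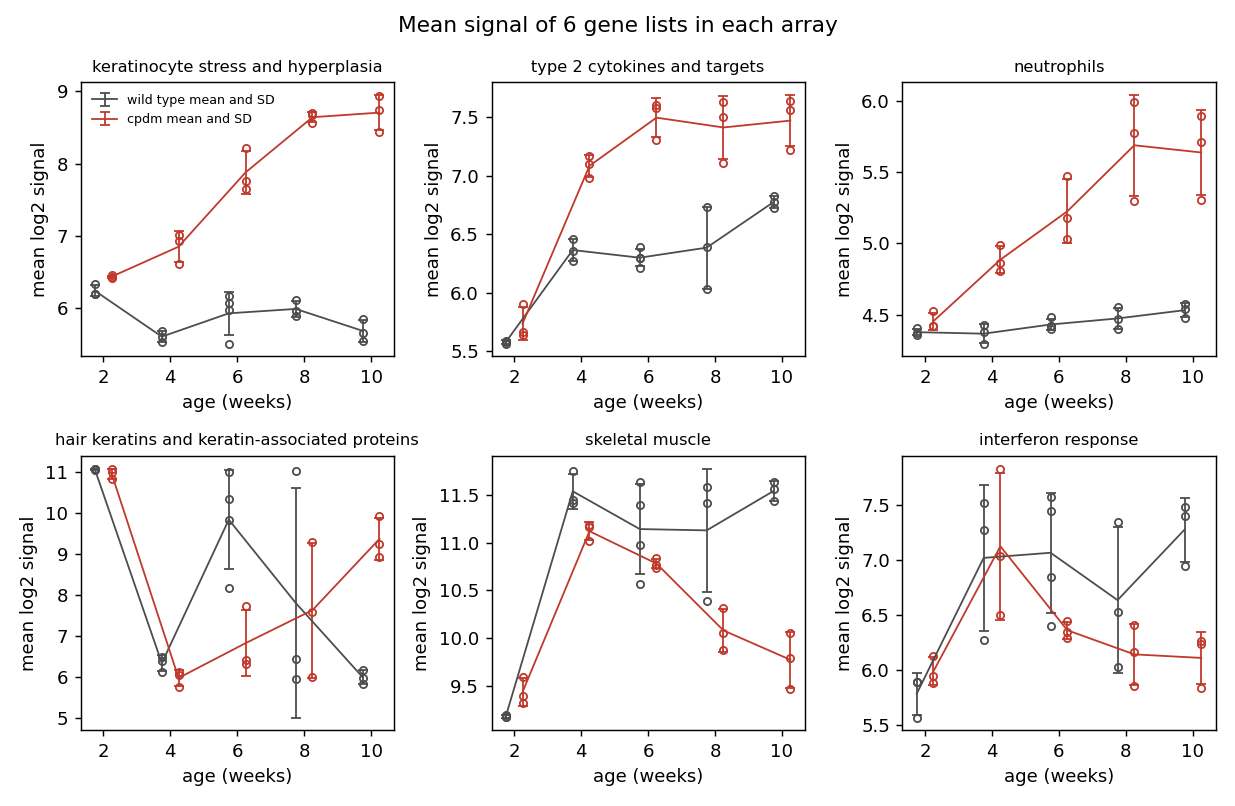
Mean log2 signal of the members of 6 gene lists (vertical axes) in each array (circles) against age in weeks (horizontal axes), with group means and standard deviations, in wild type (grey, 3 arrays per age and 4 at 6 weeks) and cpdm skin (red, 3 arrays per age). The keratinocyte stress list rises with age in cpdm skin, and in the hair keratin panel 1 wild type array at 8 weeks stands far above the other wild type arrays of that age.

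At 8 weeks, epidermal stress genes and markers of neutrophils and B cells were higher in cpdm skin, while skeletal muscle and sebaceous gland genes fell. The largest increases were Chil4 (6.74 ± 0.44), Stfa3 (5.82 ± 0.43), Gsdmc (5.44 ± 0.28), Krt6b (5.17 ± 0.46), Krt16 (4.94 ± 0.62) and Stfa2 (4.65 ± 0.29). The largest decreases were Serpina3b (-3.51 ± 0.52), the sebaceous desaturase Scd3 (-3.40 ± 0.37), Mrgprb3 (-3.08 ± 0.40), Dapl1 (-2.99 ± 0.33), the myostatin gene Mstn (-2.85 ± 0.43) and the fast myosin Myh4 (-2.68 ± 0.35). In the keratinocyte stress and hyperplasia list, 23 of 25 rose and 23 adjusted over the list alone, with a median of 2.88 (adjusted p = 4.9e-34, and adjusted p = 0.000712 with an estimated correlation). Of the neutrophil markers, 11 of 14 rose and 11 adjusted over the list alone, with a median of 1.26 (adjusted p = 6.03e-12, and adjusted p = 0.0291 with an estimated correlation), such as the chemokine receptor Cxcr2 (3.17 ± 0.22) and Ngp (2.10 ± 0.27, neutrophilic granule protein). Of the B and plasma cell markers, 9 of 11 rose and 9 adjusted over the list alone, with a median of 0.82 (adjusted p = 9.09e-11, and adjusted p = 0.0329 with an estimated correlation), such as Ms4a1 (2.24 ± 0.25, CD20), Jchain (2.14 ± 0.36) and Cd79b (1.93 ± 0.18). Of the mast cell markers, 7 of 12 rose and 1 fell over all genes, and 9 rose and 1 fell adjusted over the list alone, with a median of 0.69 (adjusted p = 2.75e-05, and adjusted p = 0.158 with an estimated correlation), Fcer1a by 1.46 ± 0.19.

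Matrix proteases rose at 8 weeks, 12 of 18 over all genes and 12 adjusted over the list alone, with a median of 1.10 (adjusted p = 3.31e-10, and adjusted p = 0.0948 with an estimated correlation). Mmp12 was higher by 3.84 ± 0.30 and the collagenase Mmp13 by 2.89 ± 0.25. Skeletal muscle genes fell, 15 of 20 over all genes and 17 adjusted over the list alone, with a median of -0.96 (adjusted p = 2.8e-10, and adjusted p = 0.3 with an estimated correlation). Sebaceous gland genes fell, 7 of 18 lower and 1 higher over all genes and 9 lower and 1 higher adjusted over the list alone, with a median of -0.56 (adjusted p = 0.00251, and adjusted p = 0.424 with an estimated correlation). With the muscle signal as a covariate, chosen after the data had been examined, that list turned to a median of 0.05 (adjusted p = 0.392). Of the 3468 genes, 1435 were higher and 2033 lower, and 568 differed at least 2-fold. That excess of lower genes did not hold with centred arrays (1752 higher and 1726 lower) or with only the arrays of 8 weeks in the fit (237 higher and 74 lower). Wild type replicate 3 stood apart from the other wild type arrays of this age, in hair keratins and in many other genes. It lay at -41.7 on the first principal component, which held 51.8% of the variance, against 40.7 and 29.5. The hair keratin list, not called at 8 weeks with all arrays (median -0.37, adjusted p = 0.811), rose by a median of 1.42 without that array (adjusted p = 8.8e-05). It fell without cpdm replicate 2 (median -1.09, adjusted p = 0.0386) or wild type replicate 1 (median -1.27, adjusted p = 0.0129). The count was 311 with only those arrays in the fit, 5273 with array weights, 2306 without wild type replicate 2 and 5126 without wild type replicate 3.

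At 10 weeks, cell division genes and hair keratins were higher in cpdm skin, and genes of muscle, fat, nerve and the interferon response were lower. The largest increases were Chil4 (6.15 ± 0.44), Stfa3 (6.13 ± 0.43), Krt16 (5.72 ± 0.62), Krt6b (5.61 ± 0.46), Sprr1b (5.46 ± 0.40) and Krt25 (5.41 ± 1.15). The largest decreases were Mstn (-4.84 ± 0.43), Serpina3b (-4.13 ± 0.52), Cyp2g1 (-3.93 ± 0.38), Myh4 (-3.88 ± 0.35), Scd3 (-3.80 ± 0.37), and the C-type lectin Cd209f (-3.70 ± 0.64). In the keratinocyte stress and hyperplasia list, 25 of 25 rose and 25 adjusted over the list alone, with a median of 2.65 (adjusted p = 1.79e-28). It was the 1 list of 21 called at this age that held with an estimated correlation (adjusted p = 0.00125). All 23 measured cell division genes rose, and 23 adjusted over the list alone, with a median of 1.02 (adjusted p = 2.75e-11, and adjusted p = 0.305 with an estimated correlation), such as the ribonucleotide reductase subunit Rrm2 (1.23 ± 0.21) and Cdk1 (1.16 ± 0.23). Of the hair keratins and keratin-associated proteins, 23 of 28 rose and 25 adjusted over the list alone, with a median of 3.49 (adjusted p = 7.03e-10, and adjusted p = 0.419 with an estimated correlation). Interferon response genes fell by a median of 1.23, 15 of 21 over all genes and 17 adjusted over the list alone (adjusted p = 0.000124, and adjusted p = 0.534 with an estimated correlation), Ifit3 by 2.49 ± 0.59 and Oas2 by 1.88 ± 0.43.

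Muscle, fat and nerve genes fell at 10 weeks. Of the skeletal muscle genes, 18 of 20 fell and 18 adjusted over the list alone, with a median of -1.66 (adjusted p = 8.26e-14, and adjusted p = 0.189 with an estimated correlation), such as Actn3 (-3.45 ± 0.29) and Pvalb (-3.28 ± 0.27). Of the adipocyte genes, 12 of 20 fell and 14 adjusted over the list alone, with a median of -0.84 (adjusted p = 0.00041, and adjusted p = 0.534 with an estimated correlation), such as Nnat (-1.99 ± 0.22) and the adiponectin gene Adipoq (-1.88 ± 0.36). Of the nerve and Schwann cell genes, 9 of 11 fell and 9 adjusted over the list alone, with a median of -0.50 (adjusted p = 0.00201, and adjusted p = 0.389 with an estimated correlation), Cnp by 1.08 ± 0.18. The lists of fibroblasts (adjusted p = 0.516), lymphatic endothelium (0.959) and pericytes and smooth muscle (0.064) were not called. The pericyte list was called lower without cpdm replicate 1 (median -0.28, adjusted p = 0.0361) or wild type replicate 1 (median -0.30, adjusted p = 0.0332). Of the 6502 genes, 2913 were higher and 3589 lower, and 1237 differed at least 2-fold. With centred arrays the majority turned, with 3479 higher and 2953 lower. With the mean signal of the muscle list as a covariate, 2032 genes were called, and the adipocyte list turned to a rise (median 0.61, adjusted p = 1.21e-05), the nerve list to a median of 0.22 (adjusted p = 0.06) and the hair keratin list to a fall (median -2.26, adjusted p = 2.66e-07). The lists of fibroblasts (median 0.51), lymphatic endothelium (1.10) and pericytes (0.53) turned to rises with it (adjusted p of 0.00133, 1.82e-06 and 0.000198). Among the genes named here, Krt25 (-0.69, adjusted p = 0.858) and Adipoq (0.44, adjusted p = 0.557) turned direction with it and were no longer called. With the mean signal of the hair keratin list as a covariate, 3343 genes were called. Muscle signal and genotype move together at this age, so a difference beside the covariate rests on the small part in which they part. Both covariates were chosen after the data had been examined.

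**Figure D3:**
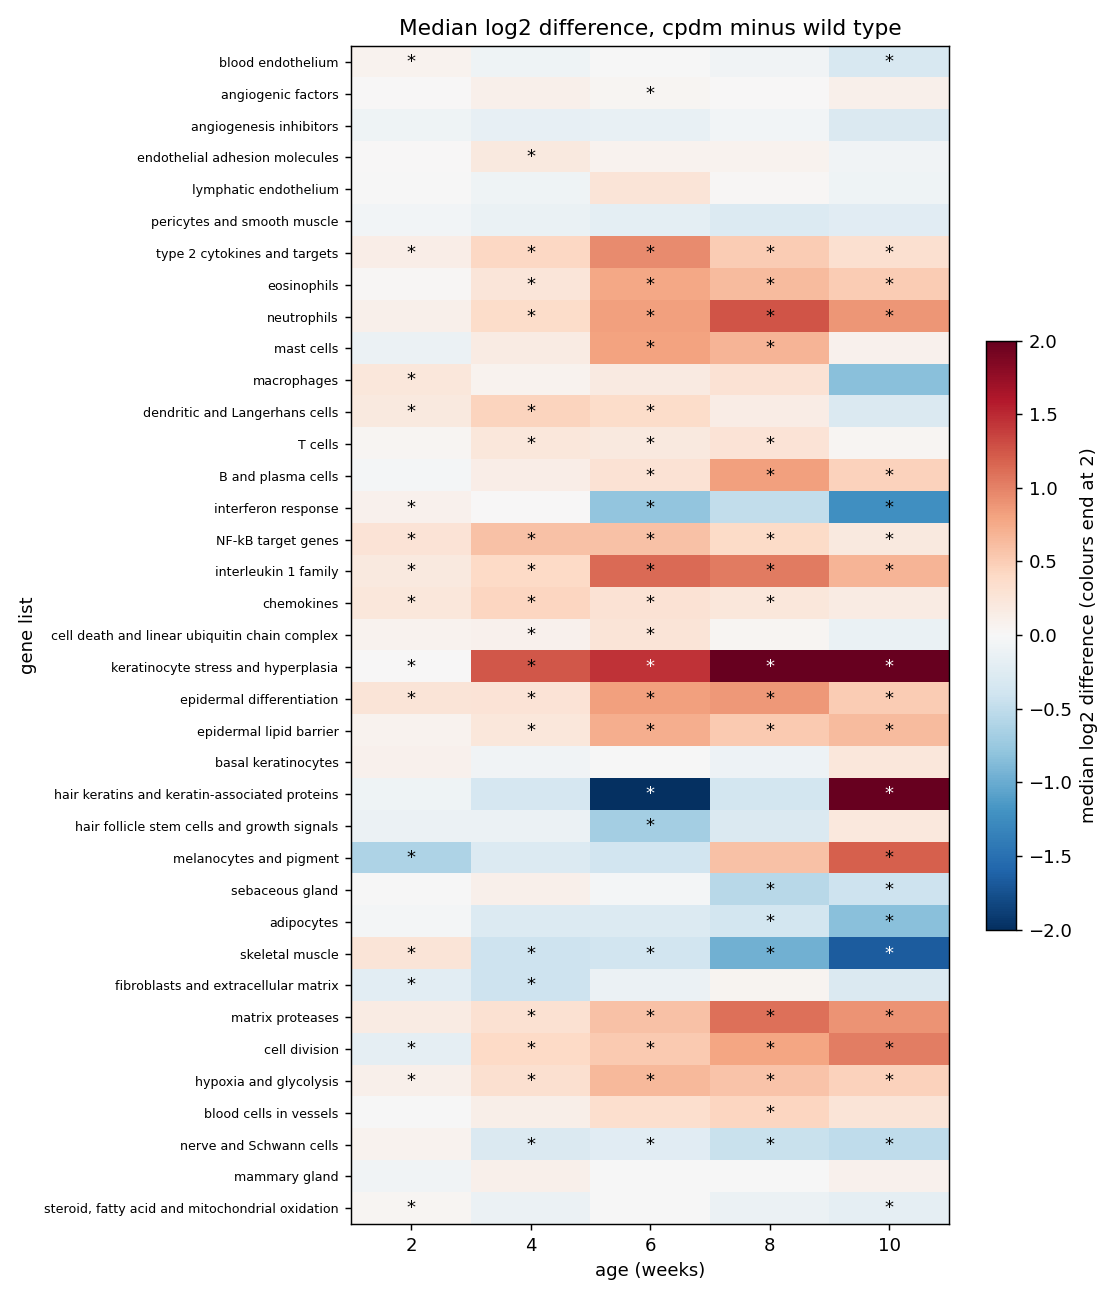
Median log2 difference, cpdm minus wild type, of 37 gene lists (vertical axis) at each age in weeks (horizontal axis), with red for higher and blue for lower in cpdm skin. An asterisk marks the 99 of 185 list tests with adjusted p below 0.05 at the preset correlation, 20 of which held with an estimated correlation, and of the 16, 19, 23, 20 and 21 calls at successive ages 10, 14, 20, 15 and 20 held with any 1 array left out.

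Most of these lists were also called at other ages. The lists of keratinocyte stress, the interleukin 1 family, NF-kB targets, type 2 responses, epidermal differentiation and hypoxia were called higher at all 5 ages. With an estimated correlation, only the interleukin 1 call held at 2 weeks and only the keratinocyte stress call at 10 weeks. In the same order, the list means differed at 2 weeks by 0.20 ± 0.15, 0.35 ± 0.13, 0.25 ± 0.11, 0.16 ± 0.14, 0.29 ± 0.13 and 0.13 ± 0.11. Neutrophils, eosinophils, matrix proteases and the lipid barrier were called higher from 4 weeks on, and B and plasma cells from 6 weeks on (adjusted p = 0.00986 at 6 weeks). T cells were called higher at 4, 6 and 8 weeks and mast cells at 6 and 8 weeks. Muscle and nerve genes were called lower from 4 weeks on, and adipocyte and sebaceous genes at 8 and 10 weeks. Cell division genes were called lower at 2 weeks (median -0.18, adjusted p = 0.0127) and higher from 4 weeks on. Melanocyte and pigment genes, called lower at 2 weeks, were called higher at 10 weeks (difference of the list means 1.02 ± 0.37). The interferon response list was called higher at 2 weeks (median 0.09, adjusted p = 0.00516), opposite to its side at 6 and 10 weeks. Its list mean differed at 2 weeks by 0.20 ± 0.34, which is within the SE. The genotype difference of that list mean did not pass the limma test of change with age (adjusted p = 0.0766). At 2 weeks macrophage markers were called higher too (median 0.22, adjusted p = 0.00131), and neither these nor the cell division and interferon calls of 2 weeks held with an estimated correlation. With 1 array left out, several calls ended: type 2 responses (adjusted p = 0.0814), macrophages (0.119), cell division (0.879) and the interferon response (0.0679) at 2 weeks, and matrix proteases (0.0649), cell division (0.232) and the lipid barrier (0.0529) at 4 weeks. So did muscle (0.0693) and nerve genes (0.21) at 6 weeks, and adipocyte (0.256), nerve (0.0725) and T cell genes (0.23) at 8 weeks.

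The series title names angiogenesis, so genes of blood vessels and vessel growth were followed at every age. Vegfa, the main vascular growth factor, was higher in cpdm skin by 0.80 ± 0.21 at 4 weeks, 1.44 ± 0.19 at 6 weeks and 1.21 ± 0.21 at 10 weeks, and it was also called at 8 weeks (adjusted p = 7.82e-05). Its receptor gene Flt1 was higher by 0.58 ± 0.18, 1.03 ± 0.17, 0.75 ± 0.18 and 0.62 ± 0.18 at 4, 6, 8 and 10 weeks. Kdr, the other receptor gene of Vegfa, lay on the opposite side: it was called lower at 8 weeks (-0.77 ± 0.22) and not called at 4, 6 and 10 weeks (-0.57 ± 0.22, -0.49 ± 0.20 and -0.52 ± 0.22). The growth factor genes Hgf (0.93 ± 0.22, 1.25 ± 0.21, 1.19 ± 0.22 and 0.88 ± 0.22) and Hbegf (0.96 ± 0.25, 1.07 ± 0.23, 2.08 ± 0.25 and 2.59 ± 0.25) were higher at the same 4 ages. Hif1a was higher from 6 weeks on (0.87 ± 0.11, 0.78 ± 0.12 and 1.13 ± 0.12), and so was the endothelial adhesion molecule Vcam1 (1.37 ± 0.21, 1.29 ± 0.22 and 0.87 ± 0.22). Tek, the angiopoietin receptor, was lower by -0.63 ± 0.17, -0.49 ± 0.16, -0.54 ± 0.17 and -1.63 ± 0.17 at 4, 6, 8 and 10 weeks, and Cd34 by -0.66 ± 0.21, -0.72 ± 0.22 and -1.21 ± 0.22 at 6, 8 and 10 weeks. Cd34 is also a member of the list of hair follicle stem cells and growth signals, so its fall need not be endothelial. The Tek ligand gene Angpt1 was lower at 8 weeks (-0.73 ± 0.21) and 10 weeks (-1.25 ± 0.21), and Angpt2 was higher at 6 weeks (0.52 ± 0.12) and 10 weeks (0.47 ± 0.13). At 2 weeks none of these genes was called by limma, with differences from -0.25 for Hif1a to 0.37 for Vcam1. Pecam1, a marker of endothelium, was not called at any age in the main comparison (0.38 ± 0.14 at 6 weeks, adjusted p = 0.0838), but was called at 6 weeks without wild type replicate 2 (adjusted p = 0.0405). With the muscle covariate, chosen after the data had been examined, Pecam1 was called higher at 10 weeks (0.62, adjusted p = 0.0299). The test of whether the genotype difference changed with age gave adjusted p = 0.00166 for Tek, 0.0125 for Vegfa and 0.000272 for Hbegf, and 0.198 for Flt1 and 0.107 for Hgf.

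**Figure D4:**
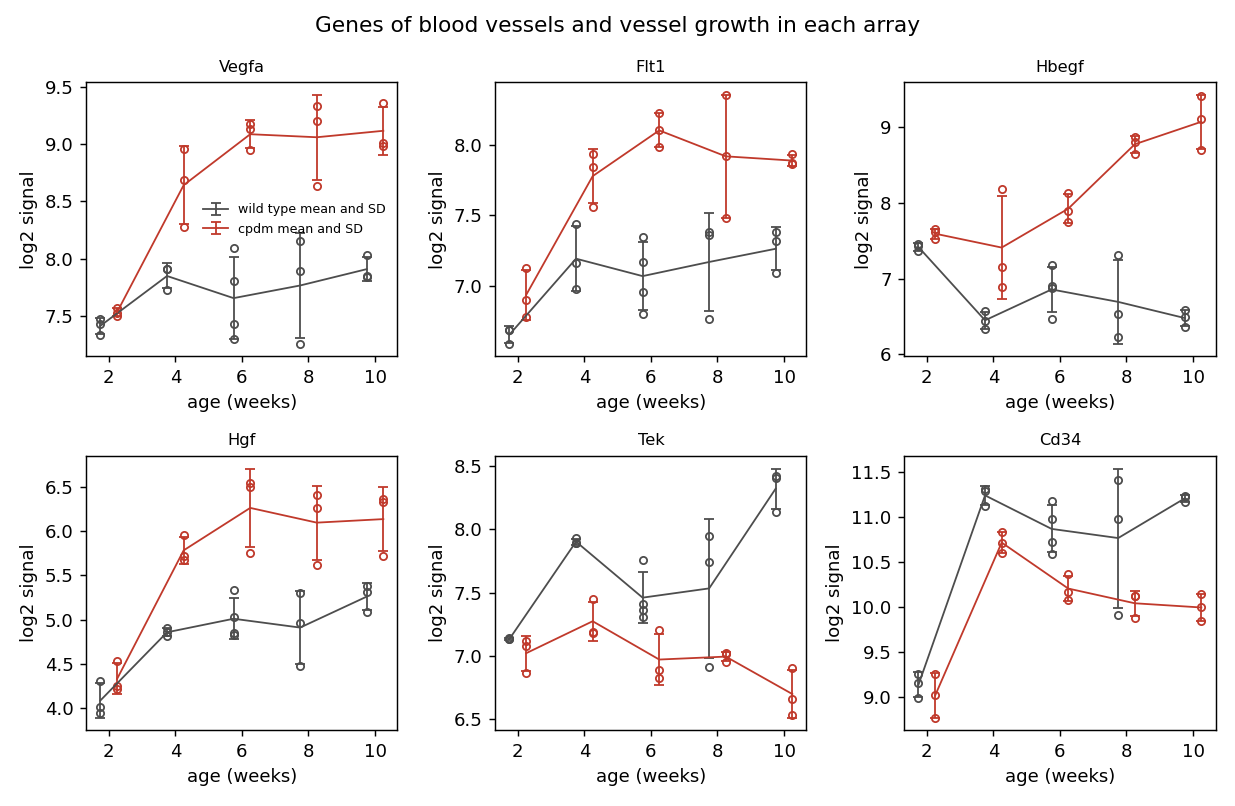
Log2 signal (vertical axes) of 6 genes of blood vessels and vessel growth in each array (circles) against age in weeks (horizontal axes), with group means and standard deviations, in wild type (grey, 3 arrays per age and 4 at 6 weeks) and cpdm skin (red, 3 arrays per age). Vegfa, Flt1, Hbegf and Hgf lie higher and Tek and Cd34 lower in cpdm skin at the later ages. Cd34 is also a member of the hair follicle stem cell list.

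As lists, vessel genes moved in both directions. Angiogenic factors were called at 6 weeks (median 0.03, mean 0.23 ± 0.08, adjusted p = 0.0366, and adjusted p = 0.375 with an estimated correlation), with 8 of 25 members higher and 1 lower over all genes and the same numbers adjusted over the list alone. That call ended without cpdm replicate 2 (adjusted p = 0.0894) or wild type replicate 1 (adjusted p = 0.0523), without members of another list (adjusted p = 0.0538), without the dimmest 40% of genes (adjusted p = 0.306) and with centred arrays (adjusted p = 0.0508). The same list was called at 4 weeks without cpdm replicate 1 (adjusted p = 0.0209) and at 8 weeks without wild type replicate 1 (adjusted p = 0.0308). At 10 weeks 9 of its members were higher and 6 lower, 10 and 8 adjusted over the list alone, and the list was not called (adjusted p = 0.224). Blood endothelium genes were called higher at 2 weeks (median 0.07, adjusted p = 0.00386, and adjusted p = 0.579 with an estimated correlation), with 0 of 23 members called by limma over all genes or adjusted over the list alone. At 10 weeks they were lower, 9 of 23 lower and 2 higher over all genes and 11 lower and 2 higher adjusted over the list alone, with a median of -0.32 (adjusted p = 0.00558, and adjusted p = 0.579 with an estimated correlation). Besides Tek and Cd34, Aplnr (-0.91 ± 0.15) and Clec14a (-0.49 ± 0.10) were among the lower members, and Flt1 and Ecscr (0.48 ± 0.16) were the higher ones. With the hair keratin or the muscle signal as a covariate, that list turned higher at 10 weeks (medians of 0.12, adjusted p = 0.445, and 0.36, adjusted p = 0.000547), and with the muscle covariate also at 8 weeks (median 0.22, adjusted p = 0.000363). Blood endothelium was called lower at 4 weeks without cpdm replicate 1 (adjusted p = 0.0465) and at 8 weeks without wild type replicate 3 (adjusted p = 0.00116). Angiogenesis inhibitors were not called at any age, and endothelial adhesion molecules only at 4 weeks (median 0.19, adjusted p = 0.0328, and adjusted p = 0.439 with an estimated correlation). With 1 of 11 adhesion members called over all genes and 4 adjusted over the list alone, that call ended without cpdm replicate 1 (adjusted p = 0.0885) or wild type replicate 1 (0.0709). Tek turned direction with the muscle covariate at 8 weeks (0.01, adjusted p = 0.975). The genotype difference of the list means did not pass the test of change with age for angiogenic factors (adjusted p = 0.407) or blood endothelium (adjusted p = 0.169).

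Many calls of vessel genes with small differences were lost without single arrays, mostly with differences of similar size. At 4 weeks, Vegfa was not called without cpdm replicate 2 (adjusted p = 0.122), cpdm replicate 3 (0.0721) or wild type replicate 2 (0.0824), with differences of 0.64 to 0.77 against 0.80. Flt1 was not called without cpdm replicate 2 (0.143) or 3 (0.162) or wild type replicate 2 (0.122) or 3 (0.152), with differences of 0.48 to 0.57 against 0.58. Hgf was not called without cpdm replicate 3 (0.067), with a difference of 0.84 against 0.93. Hbegf moved more, to 0.57 against 0.96 without cpdm replicate 3 (adjusted p = 0.15), and was not called without wild type replicate 2 either (0.0759). Tek lost its call at 4 weeks without any 1 array other than cpdm replicate 1 (adjusted p of 0.056 to 0.102), with differences of -0.64 to -0.58. It lost its call at 6 weeks without any 1 array other than cpdm replicate 1 or wild type replicate 4 (0.0525 to 0.173), with differences of -0.52 to -0.39. At 8 weeks Tek lost it without any 1 array other than wild type replicate 3 (0.0609 to 0.222). Cd34 lost it at 6 weeks without cpdm replicate 2 (0.0933) or 3 (0.137) or wild type replicate 2 (0.0911) or 4 (0.0712), and at 8 weeks without cpdm replicate 2 (0.0867) or wild type replicate 1 (0.213) or 2 (0.108). Kdr lost it at 8 weeks without cpdm replicate 1 (0.0701) or 2 (0.0538) or wild type replicate 1 (0.127) or 2 (0.0843). Without wild type replicate 1 the differences at 8 weeks were smaller, -0.33 for Tek, -0.40 for Cd34 and -0.51 for Kdr. Without wild type replicate 3, the array that stood apart at 8 weeks, they were larger, -0.85 for Tek, -1.15 for Cd34, -1.15 for Kdr and -1.08 for Angpt1. Angpt1 lost its call at 8 weeks without cpdm replicate 3 (0.0535) or wild type replicate 1 (0.0875) or 2 (0.119), with differences of -0.68 to -0.53. Ecscr lost it at 10 weeks without cpdm replicate 1 (0.0708) or 3 (0.0826) or wild type replicate 1 (0.0587) or 3 (0.112), with differences of 0.38 to 0.46. The 10-week calls of Vegfa, Flt1, Hgf, Hbegf, Hif1a, Vcam1, Tek, Cd34, Angpt1, Angpt2, Aplnr and Clec14a held with any 1 array left out.

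The interaction of genotype and age asks whether the genotype difference changed between 2 weeks and the later ages. It passed for 2931 of 19939 genes (limma, adjusted p below 0.05). The lowest p belonged to the epidermal genes Rptn (repetin) and Lce3c and to Rbp2, a retinol-binding protein, followed by Adgrg7, Klk13, Pla2g4e, Sprr2e, Casp14, Chil4 and Sprr2g. The Rptn signal in cpdm skin went from 6.01 ± 0.21 (SD, n = 3) at 2 weeks to 6.97 ± 0.37 at 4 weeks, 9.34 ± 0.45 at 6 weeks and 10.29 ± 0.15 at 10 weeks, against 5.94 ± 0.37 in wild type skin at 10 weeks. Lce3c went from 5.64 ± 0.05 at 2 weeks to 9.98 ± 0.26 at 10 weeks in cpdm skin, against 5.42 ± 0.40 in wild type skin at 10 weeks. Chil4 stood at 4.65 ± 0.29 at 4 weeks and at 10.11 ± 0.84 at 6 weeks in cpdm skin. Among list means, keratinocyte stress and hyperplasia changed most clearly with age, from a genotype difference of 0.20 ± 0.15 at 2 weeks to 3.02 ± 0.15 at 10 weeks (adjusted p = 3.45e-10). With 1 array left out, the interaction count ranged from 1965 without cpdm replicate 3 of 10 weeks to 5224 without wild type replicate 3 of 8 weeks. It was 7461 with array weights.

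The time course within each genotype asks how the skin changed after 2 weeks. In wild type skin 8596 genes changed with age and in cpdm skin 7049 (limma). Igf2bp3, a fetal RNA-binding protein, had among the lowest p in both: it went from 7.71 to 4.94 in wild type skin and from 7.65 to 4.93 in cpdm skin between 2 and 10 weeks. Gpx3 and Car3, a glutathione peroxidase and a carbonic anhydrase of fat and muscle, went from 6.44 to 11.02 and from 9.67 to 12.85 in wild type skin, and to 9.10 and 11.28 in cpdm skin at 10 weeks. Their genotype differences at 10 weeks were -1.92 ± 0.34 and -1.57 ± 0.20. The step from 2 to 4 weeks had the most changed genes, 9138 genes in wild type and 6625 in cpdm skin. Between 4 and 6, 6 and 8, and 8 and 10 weeks, 493, 0 and 679 genes changed in wild type skin and 303, 65 and 4 in cpdm skin. For the step with 0 genes by limma, 1416 of 19939 had an unadjusted p below 0.05, where chance alone gives a share of 0.05. The steps with 0 and 679 genes both use the wild type arrays of 8 weeks. Among these, wild type replicate 3 stood apart, at -41.7 on the first principal component against 40.7 and 29.5. How far both counts rest on that array was not tested. The 0 therefore does not show that wild type skin stayed unchanged between 6 and 8 weeks. With the hair keratin covariate 4335 genes changed with age in wild type and 3395 in cpdm skin, and with the muscle covariate 1871 and 4296.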

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

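The counts over other splits of the arrays and the position of an array between ages were set before, while the tests of Sharpin signal, hair cycle, centring, tissue share, macrophages and single arrays were chosen after the result was seen.

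In the wild type arrays at 6 weeks, the only group with 4 arrays, 1 array lay far from the other 3 for 6 of 57 named genes, by the share of the range taken by its gap. That share was 0.929 for Pla2g4e, 0.867 for Egln3, 0.854 for Chil3, 0.844 for Angpt1, 0.843 for Gsdmc2 and 0.833 for Il1f8. None of the 37 list means stood apart in this way. Chance alone sets apart about 1 in 20 groups.

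The genotype difference changed with age for 2931 genes (14.7% of all genes), among them 75 of the 103 genes named in the text, and for 20 of the 37 list means by limma. Genes were named partly for a low interaction p or a large difference in these same arrays, so their share is high by selection. The widest range of the difference over ages was 6.37 for hair keratins, followed by 2.82 for keratinocyte stress and hyperplasia, 2.02 for skeletal muscle and 1.63 for melanocytes and pigment. It was 1.2 for cell division, 1.14 for neutrophils, 1.12 for B and plasma cells, 1.05 for matrix proteases and 1.04 for type 2 cytokines and targets. It was 0.887 for hair follicle stem cells and growth signals, 0.842 for the interleukin 1 family, 0.837 for eosinophils, 0.708 for dendritic and Langerhans cells, 0.697 for mast cells, 0.687 for the epidermal lipid barrier, 0.671 for hypoxia and glycolysis, 0.664 for epidermal differentiation, 0.641 for the sebaceous gland, 0.484 for steroid, fatty acid and mitochondrial oxidation and 0.45 for NF-kB targets. Of 100 splits of the arrays, 6 gave an interaction count as large as the real one, the real split included, so chance cannot be excluded for that count (2931, against 4976 in the highest other split). These splits exchanged genotype labels within each age. A split that keeps or flips the labels at some ages only can turn a steady genotype difference into a changing one. Splits with more calls than the real one therefore point to no cause, and the splits cannot decide on the interaction.

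The count at 6 weeks passed the bound of a share under 0.05 (1 of 35 splits, the real one, gave 2881 genes, and the highest other gave 1698). That is the smallest share that 35 splits can give, and several counts were tested in this way without correction. Chance is thus made less likely but not excluded. The highest other split put wild type replicates 1, 3 and 4 together. The bound was also passed by the age effect in wild type skin (1 of 100 splits, 8596 genes against 4956) and in cpdm skin (1 of 100 splits, 7049 genes against 3596). At 2, 4, 8 and 10 weeks the 10 splits are too few for a share under 0.05. The real split gave 11, 1378, 3468 and 6502 genes there, and the highest other split 0, 0, 2665 and 0 by limma. The split of 8 weeks with 2665 genes exchanged cpdm replicate 3 with wild type replicate 3, which points to a structure of these arrays other than genotype.

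Among 13767 probe sets without a single gene name, 4 differed at 2 weeks, 68 at 4 weeks, 197 at 6 weeks, 393 at 8 weeks and 996 at 10 weeks (limma, adjusted p below 0.05).

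Hair keratin signal differed widely among arrays of the same age. Wild type replicate 3 of 8 weeks had a list mean of 11.02, against 5.95 and 6.44 in the other wild type arrays of that age. Over 1058 genes that differ between the ages, that array stood at 0.49 on a line from wild type skin of 6 weeks (0) to 2 weeks (1). That is only just under the bound of 0.5 set before, and about midway, far from the 2-week arrays (0.986 to 1.02) and outside the 6-week arrays (-0.126 to 0.146). The genes and both ends of the line came from these same 2- and 6-week arrays, so their narrow ranges are partly fixed in advance. No 2-week array left out of the line was placed on it. The position therefore argues only weakly against a 2-week-old mouse, and the array does not lie with the 6-week arrays either. Its Sharpin signal of 7.98 lay above every cpdm array (highest 7.58), which argues against a cpdm mouse. Deviations of hair keratin and melanocyte signal from the group means correlated at r = 0.586 (permutation p = 0.0676, rho = 0.457, permutation p = 0.0594, 1 relation computed; r = 0.388 without the 2 farthest arrays). A phase of the hair cycle that differed between mice of one age may be a cause but stays open, since the correlation did not pass. The requirement of a permutation p below 0.05 was added after the correlation was seen.

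The blood endothelium list was lower at 10 weeks. Centring each array on its median left that call (adjusted p = 0.003, median -0.26). Camera compares list members with all other genes, so an offset shared by all genes of an array largely cancels. Centring therefore cannot decide on an offset between arrays. Of the 7 lists of tissue below the epidermis, 4 were called lower and 0 higher by camera. The lists of fibroblasts and lymphatic endothelium were not called, with differences of their list means of -0.05 ± 0.19 and -0.13 ± 0.19. None of the 4 calls held with an estimated correlation (adjusted p = 0.579 for blood endothelium, 0.189 for muscle, 0.534 for adipocytes and 0.389 for nerve), and the pericyte list was also called lower without cpdm replicate 1 (adjusted p = 0.0361) or wild type replicate 1 (0.0332). A smaller share of such tissue in cpdm samples, for instance beside a thicker epidermis, could lower vessel genes without fewer vessels per tissue. This cannot be told apart from a loss of endothelium, because the share of tissue layers was not measured.

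The interferon response list was called lower at 6 and 10 weeks, though not with an estimated correlation (adjusted p = 0.579 and 0.534). At 2 weeks it was called higher (median 0.09, adjusted p = 0.00516), as were macrophage markers (median 0.22, adjusted p = 0.00131), neither with an estimated correlation. The interferon list mean differed at 2 weeks by 0.20 ± 0.34, and its genotype difference did not pass the limma test of change with age (adjusted p = 0.0766). At 8 weeks the interferon list was not called (median -0.493, adjusted p = 0.0583), but it was called lower without cpdm replicate 1 (0.00999) or wild type replicate 2 (0.0398) or 3 (0.00642). Fewer macrophages could lower it, but macrophage markers had medians of 0.185 at 6 weeks (SE of the list mean difference 0.298) and 0.293 at 8 weeks (SE 0.318), which leaves the question open. At 8 weeks they were called higher without cpdm replicate 2 (median 0.504, adjusted p = 0.0315) or wild type replicate 1 (median 0.833, adjusted p = 0.000628), which goes against fewer macrophages but rests on which array is left out. At 10 weeks their median was -0.843 and the list was not called, but it was called lower without wild type replicate 2 (median -1.16, adjusted p = 0.0067), which leaves it open too. No 1 array decided the interferon call at 10 weeks: the highest adjusted p with 1 array left out was 0.00113. A biological difference between the genotypes stays among the open explanations.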

How the results depend on the processing

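The hair keratin and muscle covariates were chosen after seeing the data, and the tests of all other alternatives before. The cause of the changes given here was not tested. With only the arrays compared in the fit, 32 genes were called at 2 weeks, 1779 at 6 weeks and 311 at 8 weeks. Array weights gave 59 genes at 2 weeks, 2925 at 4 weeks, 5273 at 8 weeks and 7461 for the interaction. Genes called with a change of at least 2-fold, fewer by construction, were 3, 182, 528, 568 and 1237 from 2 to 10 weeks. At adjusted p below 0.01, again fewer by construction, 0, 408, 1480 and 1877 genes were called from 2 to 8 weeks by limma, 1007 for the interaction and 4659 for age in cpdm skin.

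With the replicate block, 0 genes were called by limma at 2 weeks, 877 at 4 weeks and 1230 for the interaction, and the counts at 6, 8 and 10 weeks stayed within 1.5 times. The numbers did not pair the arrays: deviations of same-numbered arrays correlated at r = -0.561 to 0.264, above 0.1 in 3 of 15 pairs, and best with their own number in 6 of 15.

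With 1 array left out, the counts ranged from 0 to 4 at 2 weeks, 618 to 1064 at 4 weeks, 1457 to 2738 at 6 weeks, 2306 to 5126 at 8 weeks, 5290 to 5844 at 10 weeks and 1965 to 5224 for the interaction. The median of angiogenic factors ranged from 0.017 to 0.18 at 4 weeks, -0.015 to 0.12 at 6 weeks and -0.023 to 0.098 at 8 weeks. That of blood endothelium ranged from -0.15 to -0.065 at 4 weeks and -0.28 to -0.0033 at 8 weeks, and that of hair keratins from -1.27 to 1.42 at 8 weeks.

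The call of angiogenic factors at 6 weeks ended without the dimmest genes (median 0.025), with centred arrays (0.06), with an estimated correlation (0.033), without members of another list (0.029) and with the hair covariate (0.024). The list became called at 8 weeks with fry (0.0067) and at 4, 8 and 10 weeks with the muscle covariate (0.17, 0.18 and 0.20), and at 10 weeks with the hair covariate (0.13). Blood endothelium lost its calls at 2 and 10 weeks with an estimated correlation (0.067 and -0.317), and at 2 weeks with fry (0.067) and the muscle covariate (-0.037). It became called with array weights at 8 weeks (-0.256) and with the hair covariate at 4 and 6 weeks (-0.118 and -0.308). It reversed with the hair covariate at 10 weeks (0.115) and with the muscle covariate at 8 and 10 weeks (0.224 and 0.356).

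Hair keratins reversed at 8 weeks with array weights (0.691). At 2 weeks with only the arrays compared, their median was the same (-0.092) and only the direction of the test turned. The hair covariate gave 31, 2922, 3660, 4634 and 3343 genes from 2 to 10 weeks. It gave 4335 and 3395 for age in wild type and cpdm skin. It reversed at 10 weeks the lists of lymphatic endothelium (0.554), hair follicle (-0.419) and fibroblasts (0.17), the direction of the test but not the median for melanocytes (0.256), and Krt26 at 6 weeks (0.010), a hair keratin itself. The muscle covariate gave 24, 1514, 3797, 2975 and 2032 genes from 2 to 10 weeks. It gave 1871 and 4296 for age in wild type and cpdm skin. It reversed at 10 weeks the lists of adhesion molecules (0.398), lymphatic endothelium (1.10), pericytes (0.530), dendritic cells (0.564), hair keratins (-2.26), hair follicle (-0.783), melanocytes (-0.022), sebaceous gland (0.192), adipocytes (0.612), fibroblasts (0.507), nerve (0.224) and steroid oxidation (0.248). At 8 weeks it reversed pericytes (0.257), sebaceous gland (0.049), adipocytes (0.584), nerve (0.228) and steroid oxidation (0.201), and at 2 weeks steroid oxidation (-0.063). Of named genes it reversed Tek at 8 weeks (0.014) and Adipoq (0.441), Krt25 (-0.687), Nnt (0.285) and Pecam1 (0.617) at 10 weeks. Among these only Pecam1 was called with it (limma, adjusted p = 0.0299). Without a turn of direction, 24 calls of named genes ended and 6 were gained with the muscle covariate. With the hair covariate 10 ended and 12 were gained. Of 99 list calls, 75 were kept in every alternative but fry, the estimated correlation and the covariates. With the hair covariate 82 of 97 were kept and with the muscle covariate 76 of 94. At 2 weeks, centring gave 8 genes higher and 1 lower, against 8 and 3.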
